A study of Mus musculus with 6 samples.

How the data were processed

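Whole tongues with tumours from 6 C57BL/6 mice, 3 labelled HuR wild type and 3 labelled HuR knockout, were exposed to 4-nitroquinoline 1-oxide, and total RNA was made into Illumina TruSeq RNA libraries, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and the columns of the tables were matched to samples by the sample identifiers in the labels. Nothing says how the replicates of a group arose beyond their labels, so p-values measure the spread between these samples.

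The authors deposited 3 tables with the same 24067 genes, 1 with all 6 libraries and 2 with 4 libraries each. Each holds raw read counts per gene, which the authors did not normalise, since they are whole numbers that sum to between 29543352 and 51520707 per library. Beside the counts, per the file headers, stand the mean normalised count per gene, a signal of counts divided by DESeq2 size factors, a log2 fold change with its standard error on the log2 scale, a test statistic, which is a score, and a p-value with its adjusted p-value, all from the authors' DESeq2 comparison. Per the submitters' processing notes the tools were HTSeq and DESeq2 and the builds hg19 and mm10. The role of each, the aligner, the annotation and the strand setting are not given in the sources used here, and the symbols in the files are mouse symbols. The deposited log2 fold changes lay within a median of 2.26e-05 of those from DESeq2 with a shrinkage prior on the same counts, and within 0.0196 of those without one. Reads from overlapping or antisense genes cannot be told apart without a stated strand setting. Reads of near-identical copies, such as the Sprr2 genes, beta-defensins, stefins and ribosomal protein pseudogenes, may be split or lost, and such genes are uncertain. Coordinates are those of RefSeq for GRCm38, the assembly called mm10, matched by the gene identifiers in the files (23714 of 23795 identifiers matched). Of the symbols, 5 occur a second time and were kept as separate rows.

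Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (at least 10 counts, scaled to library size, in the smaller group and 15 in all), which left 15903. Library sizes were scaled by TMM, with factors of 1.06, 1.09 and 1.03 for KO replicates 1, 2 and 3 and 1.04, 0.936 and 0.866 for WT replicates 1, 2 and 3. A quasi-likelihood model with robust dispersion and group as its only term was fitted to the 6 libraries, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 20.7%. Standard errors of edgeR fold changes were taken as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. They, and the intervals built on them, are therefore approximate, above all at low counts. Levels per library are CPM, counts scaled by the TMM-adjusted library size. Intervals are at 95% and use the degrees of freedom of the moderated test. Normalised log2 values for list means and figures of spread used a prior count of 2.

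At these depths a gene at 1 CPM has 25.6 (WT replicate 3) to 53.0 (KO replicate 3) counts, and below that level counting error adds to the spread between animals. Comparisons of a single value used 2-sided exact permutation tests, which cannot go below p = 0.1 for 3 against 3 libraries.

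The comparison, the test, the alternatives and 32 gene lists of cell types, pathways and processes were fixed before the data were examined. The lists hold 658 genes, of which 3 were matched by an alias and 13 were absent from the tables. They are the Hu family, HuR-bound transcripts from the literature, RNA-binding regulators of AU-rich elements, basal, suprabasal, hard and wounded or tumour keratinocytes, cell cycle, p53 targets, apoptosis, epithelial-mesenchymal transition, hypoxia, xenobiotic stress, cytokines, interferon response, MHC class II, T and NK cells, B and plasma cells, myeloid cells, fibroblasts, fast muscle, slow muscle, adipocytes, salivary glands, taste buds, endothelium, Schwann cells, erythroid cells, immediate early genes, oxidative phosphorylation, ribosomal proteins and sex-linked genes. Sets with at least 4 measured members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 31 lists tested, and again with an estimated correlation and with fry. Counts within a list are given over all genes and adjusted over the list alone.

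Genes were named by a rule also fixed before. Elavl1 came first. Next came the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, non-overlapping groups and a mean of at least 1 CPM, leaving out, by their symbols, unnamed gene models, pseudogenes with a -ps suffix and antigen receptor segments. The annotated class of a gene was not used, so Sprr2g, annotated as a transcribed pseudogene, stayed in. Last came up to 4 members of each list with the smallest adjusted p past the threshold, or, where fewer than 2 passed, the 2 with the smallest unadjusted p. Genes named after their values were seen are marked as such.

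Alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, size factors by RLE or total library size only, no filter (at least 1 count), a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, the leaving out of each library in turn, the 4 libraries of each smaller table, and the mean of the fast muscle or basal keratinocyte list as a covariate. The sex of the animals as a covariate was added after the data were seen. Alternatives planned for values other than counts did not apply. Total library size moved the median log2 fold change of all genes from 0.02 to 0.18, so directions of lists were also read under it. The medians of the B and plasma cell and taste bud lists changed sign there, and no list that passed changed direction under RLE or total library size.

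No library was a copy of another, since the least different pair had a chi-square per degree of freedom of 50.3 over genes with at least 20 counts in the pair. Correlations of log2 values were 0.964 to 0.987 within groups and 0.927 to 0.984 between groups. The first principal component held 69.1% of the variance, with KO replicates 1, 2 and 3 at 45.6, 43.4 and 31.2 and WT replicates 1, 2 and 3 at 0.365, -42.5 and -78.1. The labels give no batch.

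The fit was tested on simulated data with 15903 genes, the means and library sizes of these 6 libraries and 3 against 3, where 100 genes were changed by a log2 of 1 and 100 by a log2 of 2. edgeR recovered 61% and 99% of them with 16 false among 176 calls, DESeq2 72% and 99% with 50 false among 221, and limma-voom 58% and 99% with 13 false among 170. The simulated genes varied independently of each other, so these rates need not hold in libraries whose genes vary together. Shared calls of the smaller deposited tables were set beside the mean of 5 simulations without a difference. Figures were drawn with matplotlib 3.10.9.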

Results

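RNA-seq gene counts were analysed for 6 tongues of C57BL/6 mice, 3 labelled HuR wild type (WT) and 3 labelled HuR knockout (KO). HuR, encoded by Elavl1, is an RNA-binding protein that binds AU-rich elements in messenger RNAs. The mice had been given 4-nitroquinoline 1-oxide, an oral carcinogen that damages DNA, for 16 weeks and were kept for a further 12 weeks, to an age of about 34 weeks. Each library held whole tongue with tumour rather than tumour cells alone. Total gene counts were 43256667, 34754246 and 51520707 for KO replicates 1, 2 and 3, and 33600002, 51280006 and 29543352 for WT replicates 1, 2 and 3. The comparison asked which transcripts differed between tongues labelled as with and without HuR after the carcinogen. Below, levels are normalised read counts scaled to a common library size (CPM), with the SD over 3 libraries. Fold changes are log2 of labelled KO over labelled WT with their standard error. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

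Elavl1 itself was not lower in the libraries labelled KO. It stood at 65.0, 59.3 and 78.4 CPM in KO replicates 1, 2 and 3 and at 61.7, 55.8 and 48.0 CPM in WT replicates 1, 2 and 3, from 2983, 2243, 4156, 2153, 2675 and 1227 counts. The means were 67.6 ± 9.81 CPM in the libraries labelled KO and 55.1 ± 6.91 CPM in those labelled WT (SD, n = 3), and the groups overlapped (exact permutation p = 0.2, 2-sided, where 3 against 3 cannot go below 0.1). The log2 fold change was 0.29 ± 0.15 (95% interval -0.05 to 0.64, edgeR adjusted p = 0.180), which for the fold is an interval of 0.966 to 1.55. Elavl1 is a protein-coding gene (identifier 15568) at chromosome 8, 4284781 to 4325140 in GRCm38/mm10. The counts cover the whole gene, so a deletion that leaves most exons transcribed would not be seen in them, and loss in part of the cells of a tongue would be diluted. Because the counts of the targeted gene do not show the loss that the label names, groups are called labelled KO and labelled WT throughout. Each direction is that between the labels.

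**Figure D1:**
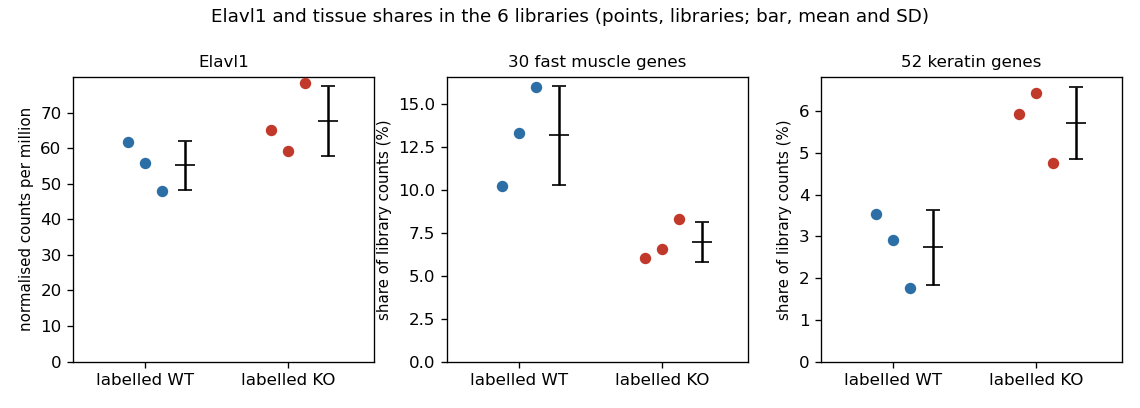
Elavl1 in normalised CPM (left), and the shares of all counts in percent held by 30 fast muscle genes (middle) and by 52 keratin genes (right), with 1 point per library and the mean ± SD of 3 libraries beside them. Elavl1 overlaps between the groups, while muscle shares run from 6.02 to 8.29% in the libraries labelled KO and from 10.2 to 16.0% in those labelled WT.

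Among genes past the threshold whose groups did not overlap and whose mean was at least 1 CPM, Mcpt1, a protease of mucosal mast cells, rose most in the libraries labelled KO. It stood at 5.89 ± 2.67 CPM against 0.116 ± 0.0995 CPM in the libraries labelled WT (log2 fold change 5.67 ± 0.59, edgeR adjusted p = 0.0295), and its neighbour Mcpt2 at 2.92 ± 0.962 against 0.154 ± 0.215 CPM (4.25 ± 0.75). Both mast cell values rest on few counts in the libraries labelled WT, with 8, 2 and 2 counts of Mcpt1. The Sprr2 genes encode small proline-rich proteins of the cornified envelope, except Sprr2g, which is annotated as a transcribed pseudogene. Sprr2b rose from 12.2 ± 16.9 to 286 ± 127 CPM (4.55 ± 1.06), Sprr2e by 4.39 ± 0.80, Sprr2f by 4.15 ± 0.90, Sprr2g by 3.67 ± 0.73 and Sprr2h by 3.38 ± 0.85 on the log2 scale. These Sprr2 genes are near-identical copies on chromosome 3, so the split of reads among them is uncertain. The amino acid transporter Slc6a14 rose from 1.28 ± 1.23 to 17.8 ± 2.63 CPM (3.77 ± 0.60, edgeR adjusted p = 0.0295). The natriuretic peptide gene Nppb (3.89 ± 0.47), lactoferrin, Ltf (3.66 ± 0.48), the beta-defensin Defb3 (7.14 ± 8.18 to 75.8 ± 28.3 CPM) and the serine protease Klk6 (3.32 ± 0.57) completed the 12 largest rises. Beta-defensin genes also have close copies, so their values are uncertain.

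The largest fall among such genes was in Slc15a2, a proton-coupled peptide transporter, which stood at 0.719, 0.608 and 0.264 CPM in KO replicates 1, 2 and 3 and at 19.8, 48.6 and 28.3 CPM in WT replicates 1, 2 and 3. Its log2 fold change was -5.94 ± 0.47 (edgeR adjusted p = 0.0245, the smallest of all genes tested), and the gene (identifier 57738) lies at chromosome 16, 36750161 to 36785158 in GRCm38/mm10. Actc1, the cardiac alpha-actin, fell from 852 ± 346 to 139 ± 17.1 CPM (-2.62 ± 0.33, edgeR adjusted p = 0.0295). H19, an imprinted long non-coding RNA, fell from 1400.0 ± 927 to 334 ± 63.9 CPM (-2.07 ± 0.46). Ucp3, a mitochondrial uncoupling protein of muscle, fell by 2.86 on the log2 scale (SE 0.68), with 243 CPM in WT replicate 3 against 33.1 and 60.8 CPM in WT replicates 1 and 2. The others of the 12 were Ttbk1 (-2.31 ± 0.47), B3galt2 (-2.23 ± 0.47), the linker histone Hist1h1e (-2.02 ± 0.38), Susd5 (-1.97 ± 0.28), the acetylcholine receptor subunit Chrna10 (-1.91 ± 0.25), Klhl33 (-1.90 ± 0.34), the xenobiotic-metabolising enzyme Cyp1a1 (-1.89 ± 0.33) and the neuropeptide Vip (-1.87 ± 0.50).

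Over the 15903 genes tested, 765 were higher and 1181 lower in the libraries labelled KO at an adjusted p under 0.05 (edgeR). The smallest adjusted p was 0.0245, and 873 of the 1946 calls had values of 0.04 to 0.05. The libraries labelled KO and WT did not overlap in 1945 of these 1946 genes, which selection by the same values nearly ensures. Of all genes tested 44.1% showed no overlap, where the average over all splits of 3 against 3 is 10%. Genes that vary together can raise that share in any 1 split, so the difference from 10% is not a test. At an unadjusted p under 0.05, 2897 genes were higher and 3233 lower. The number of calls depended on which libraries were kept. Without WT replicate 1 there were 2906 higher and 2938 lower genes, which held 1939 of the 1946, but 294 and 437 without WT replicate 3. There were 49 and 3 without KO replicate 3, 4 and 6 without KO replicate 1, 0 and 1 without WT replicate 2, and 0 and 0 without KO replicate 2 (edgeR, with 1993 and 2334 at an unadjusted p under 0.05). With the mean of the muscle list, the mean of the basal keratinocyte list, or the sex of the animals as a covariate, edgeR called 0 genes. At an unadjusted p under 0.05 it gave 220 higher and 224 lower genes with the muscle mean, 442 and 481 with the basal mean and 1672 and 1860 with sex, and no other tool was run with these covariates. The median absolute log2 fold change of the 1946 genes was 0.93 (median SE 0.20) without a covariate, 0.37 (SE 0.27) with the muscle mean, 0.50 (SE 0.23) with the basal mean and 1.00 (SE 0.30) with sex. By these medians the calls ended with smaller fold changes and larger errors under the tissue means, and with larger errors alone under sex. Under sex 20 gene lists passed by camera with a preset correlation, with medians of 1.36 for suprabasal and -1.26 for fast muscle genes, and 0 passed with an estimated correlation (smallest adjusted p = 0.573, 0 also at an unadjusted p under 0.05). No library labelled WT was female, so that fit compares KO replicate 1 with the libraries labelled WT. Every adjusted p here holds only for the fit without them.

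**Figure D2:**
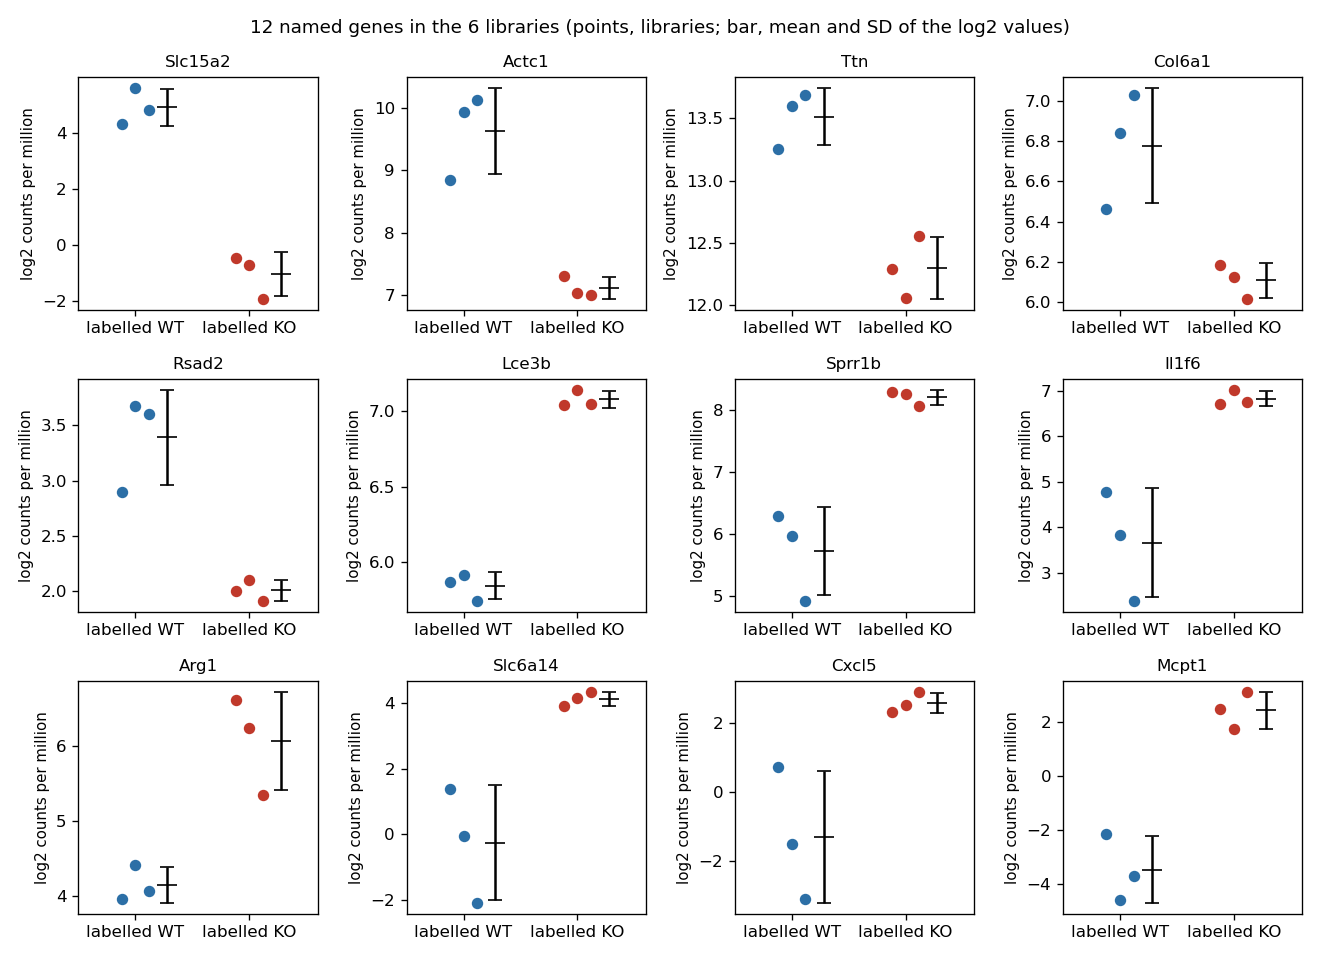
Levels of 12 named genes in log2 CPM, with 1 point per library and the mean ± SD of the log2 values of 3 libraries beside them, for libraries labelled WT (blue) and KO (red). The groups do not overlap in any of the 12, and Slc15a2 lies between 0.264 and 0.719 CPM in the libraries labelled KO.

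Genes of the differentiating upper epithelium were higher in the libraries labelled KO. Of 40 measured genes of suprabasal keratinocytes and cornification, 26 rose and 0 fell (32 and 0 adjusted over the list alone), with a median log2 fold change of 1.10. Lce3b, a late cornified envelope protein, rose from 57.4 ± 3.54 to 135 ± 5.28 CPM (1.24 ± 0.11, edgeR adjusted p = 0.0261). So did Sprr1a from 83.6 ± 30.2 to 425 ± 13.6 CPM (2.34 ± 0.26), Sprr1b from 56.8 ± 24.5 to 298 ± 24.2 CPM (2.39 ± 0.32), and Grhl3, a transcription factor of epidermal barrier formation, from 69.7 ± 7.40 to 149 ± 18.1 CPM (1.09 ± 0.14). Among 28 genes of wounded and tumour keratinocytes, 8 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 1.63. They included Il1f6, the interleukin 36 alpha gene (15.6 ± 11.1 to 114 ± 13.7 CPM, 2.87 ± 0.50), S100a7a (1.16 ± 0.19) and the beta-defensins Defb14 (1.78 ± 0.32) and Defb4 (1.22 ± 0.25). By edgeR 0 of 16 basal keratinocyte genes passed (0 adjusted over the list alone, 9 higher and 1 lower at an unadjusted p under 0.05), with a median of 0.66. DESeq2 called 6 of them higher and 1 lower, limma-voom 0 and 1, and limma-voom with quality weights 15 and 1. Over all genes limma-voom with quality weights called 3927 higher and 3846 lower, and it was not tested on simulated data. DESeq2 had 50 false among 221 calls there. Few of the simulated genes were changed and each varied independently, so those rates need not hold in the real libraries. Counts by these tools within lists, here and below, are to be read with these limits. Itga6 stood at 0.71 ± 0.22 (edgeR adjusted p = 0.0630) and Dst at -0.77 ± 0.22 (edgeR adjusted p = 0.0528). Of 12 hard keratin genes of the filiform papilla, a surface structure of the tongue, 0 passed by edgeR (0 adjusted over the list alone, 4 higher and 0 lower at an unadjusted p under 0.05), with a median of 1.23. DESeq2 called 3 of them higher, limma-voom 0 and limma-voom with quality weights 10, and each called 0 lower. Krt84 stood at 1.42 ± 0.48 and Krt31 at 1.55 ± 0.56. Without WT replicate 1 the hard keratin median was 1.96, and the list mean of KO replicate 3 (3.92 log2 CPM) lay under that of WT replicate 1 (4.48). As sets, these lists had camera adjusted p = 5.41e-15 (suprabasal), 2.39e-08 (wounded and tumour), 6.32e-04 (basal) and 0.00427 (hard keratins), all higher in the libraries labelled KO. Each of the 4 had adjusted p = 0.496 with an estimated correlation. With the muscle mean as a covariate the medians were 0.49 (suprabasal) and 0.54 (wounded and tumour), both sets still higher at the preset correlation. Basal genes did not pass there (0.01) and hard keratins passed as lower (-0.97). With an estimated correlation 0 lists passed in that fit (smallest camera adjusted p = 0.986). With the basal mean the suprabasal and the wounded and tumour medians were 0.88 and 0.49, both sets still higher at the preset correlation. Hard keratins did not pass there (0.40). With an estimated correlation 0 lists passed in that fit (smallest camera adjusted p = 0.952).

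Skeletal muscle and mitochondrial genes were lower. Of 30 fast muscle genes, 0 rose and 11 fell (0 and 26 adjusted over the list alone), with a median log2 fold change of -1.01 and all 30 below 0. Titin, Ttn, stood at 5094 ± 881 CPM in the libraries labelled KO and 11803 ± 1813 CPM in those labelled WT (-1.21 ± 0.29, edgeR adjusted p = 0.0409), triadin, Trdn, at 338 ± 54.9 and 642 ± 121 CPM (-0.92 ± 0.21), the mitochondrial creatine kinase Ckmt2 at -1.23 ± 0.29 and the calcium channel Cacna1s at -1.13 ± 0.27. Together the 30 genes held 6.96 ± 1.18% of counts in the libraries labelled KO and 13.2 ± 2.88% in those labelled WT (SD, n = 3, exact permutation p = 0.1, the smallest possible). The 52 keratin genes held 5.72 ± 0.859% and 2.74 ± 0.893% (exact permutation p = 0.1). In the list of slow muscle and myogenic genes 3 of 15 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -0.86. Those that fell were not slow fibre genes but embryonic myosin, Myh3 (-1.38 ± 0.29), the myogenic factor Myog (23.2 ± 6.82 to 11.6 ± 1.81 CPM) and the acetylcholine receptor subunit Chrna1 (-0.96 ± 0.24). Of 35 nuclear genes of oxidative phosphorylation and the citric acid cycle, 4 fell and 0 rose (32 and 0 adjusted over the list alone), with a median of -0.69. DESeq2 called 31 of them lower, limma-voom 9 and limma-voom with quality weights 33. The 4 by edgeR were Ndufs1 (-0.88 ± 0.22), Uqcrc2 (-0.83 ± 0.22), Sdhc (-0.87 ± 0.23) and Sdhb (-0.84 ± 0.23). The camera adjusted p was 5.84e-10 for fast muscle, 0.0115 for slow muscle and myogenic genes and 2.74e-09 for oxidative phosphorylation. Each had adjusted p = 0.496 with an estimated correlation. With the basal mean as a covariate the medians were -0.45 (fast muscle) and -0.22 (oxidative phosphorylation), both sets still lower, and 0.16 for slow muscle genes, which did not pass. With the muscle mean oxidative phosphorylation did not pass (0.08) and slow muscle genes passed as higher (0.44). These calls are at the preset correlation. With an estimated correlation 0 lists passed with either mean (smallest camera adjusted p = 0.952 for basal and 0.986 for muscle). Slow muscle genes did not pass without WT replicate 3 (median -0.50).

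Genes of connective tissue, vessels and nerve were also lower in the libraries labelled KO. Of 24 fibroblast and matrix genes, 8 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.51. Dermatopontin, Dpt, stood at 78.3 ± 6.01 against 136 ± 28.5 CPM (-0.80 ± 0.16, edgeR adjusted p = 0.0344), and the collagen VI genes Col6a3 and Col6a1 at -0.58 ± 0.13 and -0.69 ± 0.16, with Fap at -0.82 ± 0.19. Of 15 endothelial genes, 3 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.51: Cdh5, the cadherin of endothelial junctions (102 ± 17.5 to 58.8 ± 5.67 CPM, -0.80 ± 0.15), Kdr (-0.91 ± 0.19) and Tie1 (-0.69 ± 0.16). In the Schwann cell and nerve list, S100b (-1.02 ± 0.19) and Pmp22 (-0.62 ± 0.14) fell among 13 genes and 0 rose (2 and 0 adjusted over the list alone), with a median of -0.31. The camera adjusted p was 3.61e-04 for fibroblasts, 4.07e-04 for endothelium and 0.0185 for Schwann cells and nerve. Each had adjusted p = 0.496 with an estimated correlation. Fibroblast and endothelial sets stayed lower at the preset correlation with the muscle mean (medians -0.51 and -0.20) and with the basal mean (-0.31 and -0.27). With an estimated correlation 0 lists passed with either mean (smallest camera adjusted p = 0.986 for muscle and 0.952 for basal). Schwann cell and nerve genes passed with neither (0.10 and -0.12), nor without KO replicate 1 (-0.22), without WT replicate 3 (-0.13) or by limma-voom with quality weights (-0.36). The adipocyte list (2 of 16 fell, Plin4 by 1.31 and Lpl by 1.12 on the log2 scale, 0 rose, 3 and 0 adjusted over the list alone, camera adjusted p = 0.638) did not pass as a set. The taste bud list (2 of 9 fell, Ncam1 and Entpd2, 0 rose, 3 and 0 adjusted over the list alone, camera adjusted p = 0.397) did not pass either. The adipocyte median of -0.25 was 0.23 without WT replicate 2 and -0.39 without WT replicate 3. The taste bud median of -0.05 was 0.22, -0.28, 0.21, -0.18 and 0.12 without KO replicate 1, KO replicate 2, WT replicate 1, WT replicate 2 and WT replicate 3. Of the erythroid list 2 genes were measured, too few for a set test: Alas2, the first enzyme of haem synthesis in red cells, fell (-1.75 ± 0.38), and Bpgm stood at 0.03 ± 0.11 (1 fell and 0 rose, also adjusted over the list alone). These falls and the keratinocyte rises went together with the lower muscle share and the higher keratin share of the same libraries.

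Inflammatory genes were higher and interferon-induced genes lower in the libraries labelled KO. Of 23 cytokine and chemokine genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone), with a median log2 fold change of 1.24. Cxcl5, a neutrophil attractant, rose from 0.702 ± 0.816 to 6.02 ± 1.28 CPM (3.08 ± 0.68, edgeR adjusted p = 0.0371), Il1a from 2.54 ± 1.82 to 10.4 ± 0.432 CPM (2.02 ± 0.44), Ccl4 by 2.21 ± 0.47 and Ccl3 by 2.07 ± 0.50. Of 22 myeloid genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.52: Arg1 (17.9 ± 3.08 to 71.3 ± 28.7 CPM, 1.99 ± 0.30), the neutrophil chemokine receptor Cxcr2 (1.72 ± 0.33), Csf3r (1.28 ± 0.30) and Cd14 (0.85 ± 0.23). In the T and NK cell list Cd8b1, a chain of the CD8 co-receptor, rose (1.88 ± 0.34) among 18 genes and 0 fell (1 and 0 adjusted over the list alone), with a median of 1.08. Prf1 stood at 0.403 ± 0.0862 against 0.130 ± 0.0858 CPM (edgeR adjusted p = 0.0639). Of 9 genes of antigen presentation by MHC class II 0 passed by edgeR (0 adjusted over the list alone, 6 higher and 0 lower at an unadjusted p under 0.05), DESeq2 or limma-voom and 6 rose by limma-voom with quality weights, with a median of 0.51. H2-Eb1 stood at 0.54 ± 0.21 and H2-Oa at 1.06 ± 0.40. The camera adjusted p was 1.01e-05 for cytokines, 0.00138 for myeloid cells, 1.51e-04 for T and NK cells and 0.0303 for MHC class II. Each had adjusted p = 0.496 with an estimated correlation. Neither cytokines (medians 0.14 and -0.10), T and NK cells (0.22 and 0.25) nor MHC class II (0.02 and 0.27) passed with the muscle or the basal mean as a covariate. Myeloid genes did not pass with the muscle mean (-0.03) and stayed higher at the preset correlation with the basal mean (0.19). With an estimated correlation 0 lists passed with the basal mean (smallest camera adjusted p = 0.952). The cytokine median was 3.25 without WT replicate 1 and 0.78 without WT replicate 3, and the list mean of WT replicate 1 (1.53 log2 CPM) lay above that of KO replicate 2 (1.26). The T and NK cell median was 1.78 without WT replicate 1. MHC class II genes did not pass without KO replicate 2 (0.33) or WT replicate 2 (0.40), nor with sex as a covariate (0.35) or the filter of 1 CPM in 3 libraries (0.51). The B and plasma cell list did not pass (0 of 6 by edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 1 lower by limma-voom with quality weights, camera adjusted p = 0.823), its median of -0.05 and its mean of 0.02 having opposite signs. Its median was 0.12, -0.12, -0.62 and 0.60 without KO replicate 1, KO replicate 2, WT replicate 1 and WT replicate 3, and -0.00732 without KO replicate 3. Mzb1 stood at -0.53 ± 0.24 and Xbp1 at 0.27 ± 0.16.

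Of 27 interferon response genes, 5 fell and 1 rose (13 and 2 adjusted over the list alone), with a median of -0.61. Rsad2, an antiviral enzyme, stood at 4.02 ± 0.265 CPM in the libraries labelled KO against 10.8 ± 2.92 CPM (-1.43 ± 0.23, edgeR adjusted p = 0.0295), Usp18 at -1.09 ± 0.18, Ifi44 at -1.28 ± 0.22 and Oas2 at -1.44 ± 0.31. The fifth to fall was Ifit1 (-0.89 ± 0.23), and the gene that rose was the T cell attractant Cxcl9 (1.57 ± 0.38), both named after their values were seen. Muscle genes held 6.96% of counts in the libraries labelled KO and 13.2% in those labelled WT, and keratin genes 5.72% and 2.74%, in the tongues in which these immune and interferon genes differed. The camera adjusted p of the list was 0.00111, and adjusted p = 0.496 with an estimated correlation. The list stayed lower at the preset correlation with the muscle mean as a covariate (median -0.43) but did not pass with the basal mean (-0.16). With an estimated correlation 0 lists passed with the muscle mean (smallest camera adjusted p = 0.986). The interferon list mean of KO replicate 2 (4.13 log2 CPM) lay above that of WT replicate 1 (4.08).

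Proliferation genes were higher as a set, with 2 single calls by edgeR, in the libraries with the lower muscle share (6.96 against 13.2%) and the higher keratin share (5.72 against 2.74%). Of 44 cell cycle genes, 2 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.50 and 42 above 0. DESeq2 called 18 of them higher, limma-voom 8, limma-voom with quality weights 36, and edgeR 31 without WT replicate 1. Pcna, the sliding clamp of DNA replication, rose from 27.1 ± 5.22 to 41.5 ± 2.49 CPM (0.62 ± 0.15, edgeR adjusted p = 0.0444) and Rrm2, a subunit of ribonucleotide reductase, from 19.0 ± 8.03 to 38.3 ± 2.97 CPM (1.01 ± 0.27, edgeR adjusted p = 0.0483). The camera adjusted p was 3.24e-07, and adjusted p = 0.496 with an estimated correlation. The set did not pass with the muscle mean (median 0.16) or the basal mean (0.07) as a covariate.

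Transcripts described in the literature as bound by HuR did not fall together in the libraries labelled KO. Of 38 such genes, 1 fell, cytochrome c, Cycs (9.11 ± 1.31 to 5.39 ± 0.747 CPM, -0.76 ± 0.18, edgeR adjusted p = 0.0424), and 0 rose by edgeR (1 and 7 adjusted over the list alone, 2 and 16 at an unadjusted p under 0.05). DESeq2 called 1 lower and 13 higher, limma-voom 1 and 4, and limma-voom with quality weights 2 and 20. The median was 0.41, and Cdc6 stood at 1.47 ± 0.41 (edgeR adjusted p = 0.0515). As a set they were higher (camera adjusted p = 0.00375, and adjusted p = 0.496 with an estimated correlation), and 26 of the 38 also belong to another of the lists. The set did not pass with the muscle mean (median 0.04, the test pointing down) or the basal mean (0.08) as a covariate. Of the 4 Hu family genes 0 passed by edgeR, DESeq2 or limma-voom and 1 fell by limma-voom with quality weights (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, median -0.52, camera adjusted p = 0.373, median -0.14 without WT replicate 3), with Elavl3, mainly a neuronal gene, at -0.70 ± 0.33. The list of RNA-binding regulators of AU-rich elements, with 18 measured genes, also holds proteins that bind other sites, among them Msi2. Zfp36, a factor that destabilises messenger RNAs with AU-rich elements, rose from 46.2 ± 7.70 to 70.2 ± 6.85 CPM (0.60 ± 0.15, edgeR adjusted p = 0.0448). Msi2 fell from 169.8 ± 35.6 to 102 ± 0.892 CPM (-0.74 ± 0.17). In this list 1 gene thus rose and 1 fell (3 and 1 adjusted over the list alone), with a median of 0.20. The camera adjusted p was 0.0409, and adjusted p = 0.496 with an estimated correlation. The list passed with none of the 3 covariates (medians 0.08 for muscle, 0.05 for basal and 0.19 for sex), nor without KO replicate 3, WT replicate 2 or WT replicate 3. It passed under 7 of 19 alternatives, and DESeq2, no filter, total library size, the replicate block (median 0.21) and the libraries of either smaller table also ended the call. Its median was 0.31 without WT replicate 1.

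The remaining lists moved in part, beside the same difference in muscle share (6.96 against 13.2%). Of 18 immediate early genes, whose levels also respond to tissue handling, Btg2 (0.61 ± 0.14), Zfp36 and Ier3 (1.33 ± 0.34) rose and 0 fell (5 and 0 adjusted over the list alone, median 0.28, camera adjusted p = 0.0122, and adjusted p = 0.496 with an estimated correlation). Among 23 xenobiotic and oxidative stress genes Cyp1a1 fell and 0 rose by edgeR (1 and 0 adjusted over the list alone, 2 and 10 at an unadjusted p under 0.05). DESeq2 called 1 lower and 7 higher, limma-voom 1 and 0, and limma-voom with quality weights 3 and 9. The median was 0.89 and the set was higher (camera adjusted p = 0.0309, and adjusted p = 0.531 with an estimated correlation), with Hmox1 at 1.17 ± 0.32. Of 32 ribosomal protein genes Rpl11 rose, at the low level of 4.03 ± 0.157 against 2.32 ± 0.362 CPM (0.79 ± 0.20), and 0 fell (0 and 0 adjusted over the list alone, median 0.28, camera adjusted p = 3.61e-04, and adjusted p = 0.496 with an estimated correlation), with Rps24 at -1.13 ± 0.32. Reads of ribosomal protein genes are shared with their pseudogenes, so these values are uncertain. Xenobiotic genes passed as lower with the muscle mean as a covariate (median -0.36), at the preset correlation alone. They did not pass with the basal mean (0.04, the test pointing down), without KO replicate 1 (0.52), without WT replicate 3 (0.65) or by limma-voom with quality weights (0.77). Immediate early genes did not pass with the muscle mean (0.29), and their median was 0.19, 0.47 and 0.60 without KO replicate 1, KO replicate 3 and WT replicate 3. Ribosomal protein genes did not pass with sex as a covariate (0.15).

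Other lists did not pass the set test. Of these the salivary list passed as higher under 10 of 19 alternatives, among them those without KO replicate 1 (median 0.27), KO replicate 2 (1.45) or WT replicate 2 (1.61). The epithelial-mesenchymal transition list passed as higher under 6, among them those without KO replicate 2 (0.50) or WT replicate 1 (0.55), and its median was 0.25 without KO replicate 1. Without WT replicate 3 the medians of the p53, apoptosis and hypoxia lists were 0.05, 0.12 and -0.15, and the p53 median was 0.025 without WT replicate 2. In the p53 list 2 of 22 rose, Btg2 and Pmaip1 (3.04 ± 1.63 to 8.73 ± 2.31 CPM), and 2 fell, Ccng1 (-1.22 ± 0.21) and Rrm2b (-0.67 ± 0.16), with 3 and 2 adjusted over the list alone, a median of 0.07 and camera adjusted p = 0.710. Among 23 apoptosis regulators Bid rose (1.11 ± 0.26) and Cycs and Fas (-0.67 ± 0.18) fell, with 2 and 2 adjusted over the list alone, a median of 0.19 and camera adjusted p = 0.166. In the list of epithelial-mesenchymal transition and invasion, of 26 genes, the protease Mmp12 rose (1.84 ± 0.49) and the transcription factor Zeb1 fell (-0.80 ± 0.14), with 0 and 1 adjusted over the list alone, a median of 0.40 and camera adjusted p = 0.0738. In the hypoxia, glycolysis and angiogenesis list, of 21 genes, Adm (8.32 ± 1.64 to 25.3 ± 15.4 CPM) and Ndrg1 (0.47 ± 0.11) rose and Kdr and Bnip3 (-0.75 ± 0.19) fell, with 5 and 4 adjusted over the list alone, a median of -0.26 and camera adjusted p = 0.373. In the salivary and von Ebner gland list 3 of 13 rose and 0 fell (4 and 0 adjusted over the list alone, median 1.44, camera adjusted p = 0.0518): Ltf, Wfdc12, a protease inhibitor, from 20.5 ± 8.05 to 96.6 ± 20.2 CPM (2.23 ± 0.29), and Bpifa1, at 0.879 ± 0.598 CPM against 1, 3 and 0 counts in WT replicates 1, 2 and 3.

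The sexes of the animals, which the labels do not give, were unequal between the groups. Xist, expressed from the inactive X of females, stood at 1271 and 1104 CPM in KO replicates 2 and 3 and between 0.625 and 2.50 CPM in the other libraries. The Y-linked Uty stood at 21.5 CPM in KO replicate 1, at 32.2, 34.6 and 28.7 CPM in WT replicates 1, 2 and 3, and at 0.132 and 0.151 CPM in KO replicates 2 and 3. Of the 5 sex-linked genes Xist passed the test (9.24 ± 2.27, edgeR adjusted p = 0.0479) although its groups overlap, and 0 fell (1 and 0 adjusted over the list alone). The median of the list was -1.64, its mean was 0.45, and the set test pointed down (camera adjusted p = 0.156). The list passed as lower without KO replicate 1 (median -7.77), by limma-voom (-5.31) and with the muscle mean as a covariate (-7.35), and the median was -1.06 without KO replicate 2 and -1.05 without KO replicate 3. All libraries labelled WT were thus male by these genes, and 1 of those labelled KO.

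**Figure D3:**
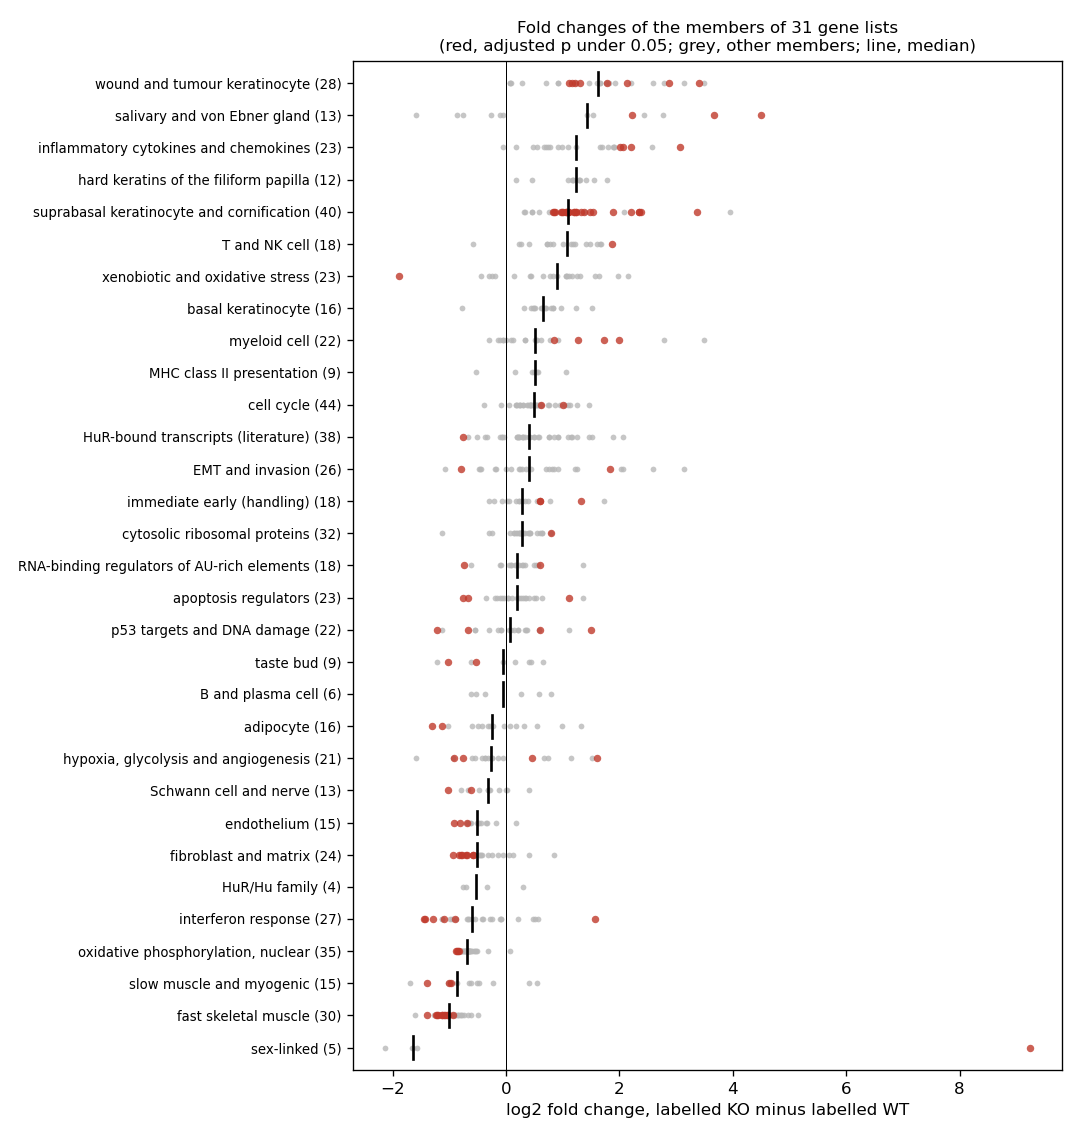
Log2 fold changes, labelled KO minus labelled WT, of the members of 31 gene lists, with 1 point per gene (red where edgeR's adjusted p was under 0.05) and a line at each list's median. The number of genes measured stands beside each list, and the medians run from 1.63 for wounded and tumour keratinocytes to -1.01 for fast muscle and -1.64 for the sex-linked list.

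Of the 31 lists tested, 21 passed an adjusted p of 0.05 by camera with a preset correlation of 0.01, 14 higher and 7 lower in the libraries labelled KO. With a correlation estimated from the data 0 passed (smallest adjusted p = 0.496, 0 also at an unadjusted p under 0.05), and by fry, which does not compare a set with other genes, 0 passed (smallest adjusted p = 0.0948, 9 at an unadjusted p under 0.05). The preset-correlation p-values treat members of a list as nearly independent. Scaling by total library size moved the median log2 fold change of all genes from 0.02 to 0.18. Under it the xenobiotic (median 1.02), MHC class II (0.66) and RNA-binding (0.35) lists did not pass, and the medians of the taste bud and B and plasma cell lists turned to 0.11 and 0.13. Of the lists that passed, the list means of the libraries labelled KO and WT overlapped for hard keratins, cytokines, interferon response, slow muscle, xenobiotic and ribosomal protein genes. Suprabasal, wounded or tumour keratinocyte, fibroblast and endothelial genes passed in the same direction under all 19 alternatives of the fit, by camera with the preset correlation. With an estimated correlation 0 lists passed with the muscle or the basal mean as a covariate (smallest camera adjusted p = 0.986 and 0.952).

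In the authors' deposited table of all 6 libraries, log2 fold changes are given as labelled WT over labelled KO. That direction was read from the counts, whose group means had the same sign in 99.8% of the genes with an adjusted p. The authors' deposited table lists 2468 genes higher in WT and 1875 higher in KO at an adjusted p under 0.05, of 15139 genes with a value. Elavl1 stands in the authors' deposited table at a log2 fold change of -0.27 (lfcSE 0.17, adjusted p = 0.220). The authors' deposited table of WT replicates 1 and 3 against KO replicates 1 and 2 lists 829 genes higher in WT and 501 higher in KO, and the authors' deposited table of WT replicates 2 and 3 against the same KO libraries lists 3092 and 2587. Elavl1 stands at -0.16 (adjusted p = 0.713) and -0.23 (adjusted p = 0.348) in these last authors' deposited tables.

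Both smaller tables contain WT replicate 3 and KO replicates 1 and 2, so their calls are not independent. Of 13894 genes with an adjusted p in both of the authors' deposited tables, 829 and 3024 were higher in WT and shared 820, where independent lists would share 180 and simulated libraries with no difference shared 3.8. Of those higher in KO, 501 and 2475 shared 475, against 89.2 for independent lists and 3.2 simulated, and 0 genes were called in opposite directions in the authors' deposited tables. Part of the excess over independent lists may come from the shared libraries, which are too few to be divided. The simulated libraries were shared in the same way, but their genes varied independently of each other. In the real libraries the first principal component held 69.1% of the variance. The simulated values may therefore be too low for libraries that vary along a common axis.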

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

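The sex covariate was chosen after the data were seen, and all other alternatives before. Elavl1 stayed above 0 and short of the threshold under all 19 alternatives, from 0.00 with the basal keratinocyte covariate to 0.44 with total library size, and from 0.17 without KO replicate 3 to 0.40 without WT replicate 1. Counts of genes higher and lower in the libraries labelled KO (765 and 1181) stayed within 1.5 times with limma-voom, RLE and both filters. They were 1909 and 2472 with DESeq2, 3927 and 3846 with quality weights, 406 and 468 with total library size, 2386 and 2900 in the libraries of the third table, and 0 and 0 in those of the second (1287 and 1921 at an unadjusted p under 0.05), and the cause was not tested. With covariates edgeR called 0 and 0 genes for muscle (220 and 224 unadjusted), 0 and 0 for basal keratinocytes (442 and 481) and 0 and 0 for sex (1672 and 1860). These designs leave fewer residual degrees of freedom, and the covariates move with the groups. Leaving out 1 library gave 0 to 2906 higher and 0 to 2938 lower: 4 and 6 without KO replicate 1, 0 and 0 without KO replicate 2 (1993 and 2334 unadjusted), 49 and 3 without KO replicate 3, 2906 and 2938 without WT replicate 1, 0 and 1 without WT replicate 2 (1640 and 2329 unadjusted), and 294 and 437 without WT replicate 3. Fewer samples leave fewer degrees of freedom, and why WT replicate 1 acts the other way was not tested, though it lay nearest the libraries labelled KO on the first principal component. Of the 1946 genes, 1905 had the same sign with the muscle covariate and 1945 with the sex covariate, and under the others all those tested did. The replicate block gave 1705 and 2112 genes. Deviations of same-numbered libraries correlated by 0.122, -0.157 and 0.193 and 3 of 6 libraries correlated best with their own number, so the numbers were not taken to pair animals. Gene lists past the threshold numbered 17 to 24 (main value 21, 17 to 22 with 1 library left out), except 10 with the muscle and 9 with the basal covariate, 0 with an estimated correlation and 0 with fry; the cause was not tested. Of 2389 pairs of a named gene and an alternative, 7 changed sign: with the muscle covariate Vip (0.32), Bnip3 (0.0075) and Krt31 (-0.63), with the basal covariate Xbp1 (-0.020), in the libraries of the second table Bpgm (-0.00798) and in those of the third table again Bpgm (-0.0465), and with the sex covariate Xist (-0.079). Depth limits genes under about 1 CPM.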

Other observations

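Kallikrein and Tmprss11 protease genes were higher in the libraries labelled KO, in families picked after their values were seen and not tested as sets. Of 12 measured kallikrein genes, 8 rose and 0 fell, with a median log2 fold change of 1.37. Klk9 (1.65 ± 0.18), Klk14 (71.6 ± 15.6 to 221 ± 45.3 CPM, 1.63 ± 0.22), Klk13 (1.31 ± 0.17) and Klk10 (96.8 ± 28.8 to 294 ± 41.9 CPM) belong to the serine proteases active in shedding of the epithelial surface. Of 6 Tmprss11 genes, airway-type transmembrane serine proteases, 4 rose and 0 fell, among them Tmprss11g (2.25 ± 1.01 to 14.7 ± 3.62 CPM, 2.70 ± 0.33) and Tmprss11d (1.54 ± 0.21). The claudin gene Cldn4 rose from 15.0 ± 2.30 to 42.5 ± 0.876 CPM and Il22ra1, a receptor chain for interleukin 22, from 6.28 ± 0.915 to 18.8 ± 3.62 CPM (1.57 ± 0.19). The stefin A genes Csta1 (2.31 ± 0.32), Stfa2 (3.55 ± 0.73) and Stfa3 (1.88 ± 0.28), inhibitors of cysteine proteases expressed in keratinocytes and neutrophils, rose as well, and as near-identical copies they are uncertain. In the same libraries keratin genes held 5.72 against 2.74% of counts and muscle genes 6.96 against 13.2%. With the muscle and the basal keratinocyte mean as a covariate, where edgeR called 0 genes (220 higher and 224 lower with the muscle mean and 442 and 481 with the basal mean at an unadjusted p under 0.05), the medians were 0.68 and 0.91 for kallikreins and 1.19 and 1.62 for Tmprss11 genes, and Cldn4 stood at 1.23 and 1.27, Il22ra1 at 1.12 and 1.45, Csta1 at 2.14 and 2.23, Stfa2 at 2.28 and 3.70 and Stfa3 at 1.58 and 1.62.

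Of the tests that follow, that of the slope on muscle was written before its result was seen, and the others were chosen after. The 1946 genes past the threshold were the result of 1 of the 10 splits of the 6 libraries into 3 against 3, and the highest of the other splits gave 0. With 10 splits the share cannot be under 0.05.

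Elavl1 was not lower in the libraries labelled KO. If the labels of the groups had been exchanged, Elavl1 would be lower in the libraries labelled WT, and its log2 fold change of 0.29 had a 95% interval of -0.05 to 0.64, which neither shows nor excludes this. Loss limited to keratinocytes may be hidden by more keratinocytes in these tongues, but with the basal keratinocyte mean as a covariate the fold change was 0.00227 (-0.44 to 0.44), so this explanation cannot be told apart from no loss of the transcript. A deletion that leaves a counted transcript also remains open, since exon counts were not analysed here.

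Muscle genes were lower and epithelial genes higher in the libraries labelled KO. A lower share of muscle alone, with no fibroblasts lost beside it, would raise fibroblast and suprabasal genes alike. The fibroblast list mean minus the suprabasal one differed by -1.78 (log2, 95% interval -2.61 to -0.95), which goes against that narrow form. The comparison restates a difference already seen between these lists. It cannot address a loss of muscle together with fibroblasts that lie within it. More epithelium against the tissue beneath is a candidate explanation. Slopes on the muscle mean within groups followed the fold change between groups along the same axis. The genes were those of the keratinocyte (basal, suprabasal and hard keratin), fibroblast, endothelial, slow muscle and oxidative phosphorylation lists. The last 2 lists, with 15 and 35 measured genes, may follow muscle content itself. The test therefore cannot tell more epithelium from less muscle. The correlation was r = 0.798 over genes, which are not independent replicates. Fibroblast genes did not follow this axis throughout. Their list mean fell over KO replicates 1, 2 and 3 (6.08, 5.85 and 5.79 log2 CPM) as the muscle mean rose (9.64, 9.84 and 10.26). In WT replicates 1, 2 and 3 the fibroblast mean was 6.18, 6.38 and 6.32, lowest where the muscle mean was lowest. The fibroblast median fold change was -0.51 both with and without the muscle mean as a covariate. Suprabasal minus basal means differed by 0.69 (95% interval 0.0045 to 1.37, just short of 0), so a change within the epithelium stays open. That test restates the difference that prompted it, and KO replicate 3 (-0.703) lay beside WT replicate 2 (-0.739). Whether more epithelium accounts for the whole is therefore not decided. Sex cannot be told apart: the male library KO replicate 1 lay -1.24 (log2) from the mean of the libraries labelled WT in muscle genes, and with sex as a covariate medians were -1.26 for fast muscle and 1.36 for suprabasal genes, which goes against sex as the whole, but without females labelled WT both values rest on that 1 library, and a loss of HuR, tumour size and dissection were not tested.

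Slc15a2 was near the floor in every library labelled KO and in none labelled WT. Its fold change lay -4.20 (log2, 2 SE bounds -5.40 to -2.99) beyond that of Alas2. Alas2 fell most among members of the muscle, fibroblast, endothelial, adipocyte, nerve, taste bud, erythroid and B and plasma cell lists. No member of these lists thus fell as far. Slc15a2 was picked as the largest fall, so a gap below 0 was fixed in advance. Alas2 comes from a list too small for a set test, and not all these lists fell as sets. The gap therefore does not decide whether a lower share of a tissue contributed. A variant haplotype around the gene, such as one carried with a transgene, could act on its neighbours. It would not be linked to the targeted allele, since Elavl1 lies on chromosome 8 and Slc15a2 on chromosome 16. Around Elavl1, 4 of 33 genes within 5 Mb passed the threshold (12.1%, against 12.3% elsewhere). Around Slc15a2, 7 of 28 genes within 1 Mb passed (25%, against 12.2% elsewhere, Fisher's exact p = 0.0733, 2-sided), 6 of them higher and 1 lower. That decides nothing, because a variant can act on 1 gene. The higher ones include the stefin genes Csta1, Stfa2 and Stfa3, close copies that are not separate evidence. BC100530 (3.54) and Gm5416 (3.86), also higher, lie between Csta1 and Stfa3 and may not be separate evidence either. The remaining calls were Fam162a (0.59), higher, and Fbxo40 (-1.32), lower. The effect of HuR on this transcript itself was not tested.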
